A study of Mus musculus with 20 samples.

How the data were processed

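Neurospheres are free-floating clusters grown in culture from neural stem and progenitor cells. Per the labels, RNA was taken from mouse neurospheres of the subventricular zone (SVZ) or the hippocampus (HC), each from Egfl7 knockout or wild-type donors. The 20 libraries fall into 6 groups. SVZ spheres of the first sphere round were taken at culture day 3, with 3 knockout and 3 wild-type libraries. Hippocampal spheres of the first round, called HC1 here, were taken at day 5, also 3 and 3. Hippocampal spheres of the second round, HC2, were taken at day 5, with 4 and 4. All donors were male except the 3 female HC1 wild types, so genotype and donor sex cannot be separated in HC1. The sample titles give each library of a group its own mouse number. Some numbers recur across groups: knockout mouse 1 in HC1 and HC2, knockout mouse 4 and wild-type mice 5 and 6 in the SVZ and HC2, and wild-type mice 2 and 3 in HC1 and HC2. The last 2 are female in HC1 and male in HC2, so a number does not mark 1 animal throughout. Whether other recurring numbers mark the same animal is not stated, and all libraries were treated as independent.

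Per the labels' protocols, total RNA was extracted with Trizol, depleted of ribosomal RNA, made into stranded libraries, enriched for mouse exons by hybrid capture and read as pairs on a NovaSeq. Per the submitters' processing notes, the tools included FastQC 0.11.5 and DESeq2, and the build was mm10, also called GRCm38. The aligner, the read counter, the gene lengths behind the values and the use of strand in counting are not given in the sources used here. The deposited values are linear total RPKM per gene, per the file headers: reads scaled by the length of the gene model and by the mapped reads of the library. RPKM are not counts, so no count model was run. A gene without a value in a library was read as 0 RPKM. The deposited table of all genes held 36724 genes, and a second table held the 19709 of them kept by a filter of the authors, whose rule is not given in the sources used here; each has a value in at least 8 of the 20 libraries. Both tables have the same values, and the second was used only as a gene list. Of the gene symbols, 78 were shared by several genes and were told apart by position. Gene positions are those deposited with the tables, on GRCm38.

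The groups, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. Genes with at least 0.5 RPKM in at least 3 of the 20 libraries were kept, which left 16403 genes, 44.7% of the table. Values were tested as log2(RPKM + 1), so a fold change is on that scale and understates the change of low genes. limma 3.58.1 in R 4.3.3 was fitted with 1 mean for each of the 6 groups and 14 residual degrees of freedom (lmFit, contrasts.fit, eBayes with trend and robust). All adjusted p-values of single genes are two-sided limma p-values after Benjamini-Hochberg adjustment over the kept genes, with a threshold of 0.05. Knockout was compared with wild type in the SVZ, HC1 and HC2, and as the mean of both hippocampal contrasts. The knockout effects were compared between the SVZ and HC2 and between HC1 and HC2. The regions were compared as the mean of both SVZ groups minus the mean of both HC2 groups. Region, culture day and sphere round differ together in that contrast, so SVZ knockouts were also compared with HC1 knockouts, male donors of the same round at days 3 and 5. Egfl7, Vegfd, Notch1 and, after its call was seen, Cd59a were also tested 1 gene at a time with two-sided exact permutation tests within region and round. Those exact tests cannot go below p = 0.1 with 3 against 3 libraries, 0.0286 with 4 against 4, and 0.00143 over HC1 and HC2 together.

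The 29 gene lists cover signalling pathways, neural and other cell types, immune and stress responses, metabolism, matrix and adhesion, regional genes and sex-linked genes. Of these, 27 had enough kept genes to be tested, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists of a contrast. The genes named are Egfl7, Vegfd, Notch1 and the sex-linked genes, and up to 8 called genes per direction with a group mean of at least 1 RPKM and no overlap between the groups. Added to these were 2 called members per list and direction and, where fewer than 5 genes passed, the 10 genes of smallest p as values only. For the regions the rule took 5 genes per direction and the members of 6 lists of regional and neural cell types, and for differences between knockout effects 5 per direction. Predicted genes, clones, microRNA and snoRNA genes, pseudogenes, rRNA and mitochondrial genes were counted but not named under the parts on largest changes and smallest p. Called genes of those kinds and the list members given as examples in the knockout comparisons were chosen after their values were seen. Some genes that the rule would name are not reported here.

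Depth was worked out from the values. The lowest values of 123 snoRNA genes of at most 250 bases were whole multiples, within 0.05 and up to 10 steps, of a smallest step in each library. The share of whole values was 98.1% to 100%, against 10% by chance. On the scale of the M in RPKM, the steps gave depths of 11.7 to 13.9 read units in the 12 libraries of the first round and 17.8 to 31.2 in the 8 of the second. A unit may be a read or a read pair, which the values do not tell. Egfl7 and Figf values came within 0.108 and 0.124 of whole numbers of reads, at 816 and 1009.5 bases per step. The tolerance of 0.15 for these was set after a narrower one gave no length. For microRNA genes a length between 18 and 26 bases was sought, after their values were seen. Limits for values of 0 are what 3 reads would have given, and they cover counting error only, since the reads carry no molecular identifiers.

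Libraries of 1 group correlated at r = 0.932 to 0.988 across genes over 24 pairs, and at most 0.207% of their values were identical. Pairs from different groups reached r = 0.990 and 0.494% identical values. With so few identical values, none was taken for a repeat of another. RNA types came from RefSeq through the deposited NCBI gene identifiers, which matched 95.7% of the kept genes, 13349 of them protein coding. The fits were tested on simulated data made from the real means and spreads of the 16403 genes, with 100 genes changed by a log2 of 1 and 100 by 2. At a change of 1, the fit called 66% of the changed genes in the SVZ, 76% in HC2, 73% in HC1 and 88% in both hippocampal rounds together. At a change of 2 it called 92%, 95%, 94% and 98%. For the differences of knockout effects it called 44% and 82% between the SVZ and HC2, and 53% and 90% between HC1 and HC2. For the regions it called 89% and 99%. The simulated noise was independent between genes, with 1 spread per gene over all groups. In the real data genes vary together and HC2 libraries vary more than SVZ libraries, so these shares may not hold there.

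Alternatives changed 1 choice at a time, except that the block was run in the fit on the compared groups: a pseudocount of 0.1, no filter, the authors' filtered genes, rescaling by median ratios over the 11360 genes above 1 RPKM in every library, limma's arrayWeights, a fit on the compared groups alone, the replicate number as a block, donor sex as a term (which leaves only the HC2 contrast to estimate genotype), sex-linked or X and Y genes left out, and each replicate left out in turn. Protein-coding genes alone, the mean of the cell cycle list as a covariate, and the omission of both SVZ libraries whose Egfl7 level goes against their label were added after the data had been seen. A residual principal component as a covariate was tried too and dropped, because it gave too many calls. All splits of the libraries into groups of the same sizes were refitted, or 100 of them where there were more.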

Results

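Egfl7 encodes a secreted protein with epidermal growth factor-like domains, made mainly by endothelial cells and also by neural stem cells, that binds Notch receptors. Expression was measured by RNA sequencing in 20 libraries of mouse neurospheres from the subventricular zone and the hippocampus, knockout or wild type for Egfl7. The SVZ and first-round hippocampal groups (HC1) had 3 libraries each, and the second-round hippocampal groups (HC2) had 4 each. The first-round libraries held values for 19109 to 20158 genes and the deeper second-round libraries for 20640 to 22204. Most markers of cell types outside the neural lineage were too low to be tested, with 5 of 19 endothelial, 6 of 18 pericyte and fibroblast, 3 of 20 microglia and macrophage and 0 of 5 blood markers kept. The median marker of the microglia and macrophage list lay at 0 RPKM in all SVZ and HC1 groups and at 0.0085 RPKM or below in HC2. The median endothelial marker lay between 0.0697 and 0.136 RPKM in the 6 groups, the median pericyte and fibroblast marker between 0.0289 and 0.0773, and that of the blood list at 0.

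Egfl7 itself (NCBI gene 353156, plus strand of chromosome 2, bases 26581028 to 26592682, GRCm38) was listed at 0 RPKM in all 3 HC1 and all 4 HC2 knockout libraries, where 3 reads would have given 0.301 to 0.315 and 0.118 to 0.207 RPKM. Every hippocampal wild-type library held it. The HC1 wild types had 1.34, 1.07 and 0.566 RPKM, from 14, 11 and 6 reads, and the HC2 wild types 1.16, 1.05, 1.59 and 0.996 RPKM, from 27, 22, 38 and 21 reads. The log2 difference was -0.97 in HC1 (exact permutation p = 0.1, the smallest possible), -1.13 in HC2 (exact permutation p = 0.0286, the smallest possible) and -1.05 over both rounds (exact permutation p = 0.00143). limma with shared spread did not call the gene, with an adjusted p of 0.750 over both rounds. In a fit on only the groups compared it did so, in HC2 (adjusted p = 0.0371) and over both rounds (0.00045). That fit leaves out the SVZ groups, in which Egfl7 varied widely under each label, as given next. In the SVZ, 1 library of each genotype went against its label. The library labelled SVZ knockout replicate 2 had 2.86 RPKM from 30 reads, and the library labelled SVZ wild type replicate 3 had 0, where 3 reads would have given 0.265. The other SVZ knockouts had 0.094 RPKM from 1 read and 0, and the other SVZ wild types 1.73 and 2.99 RPKM from 17 and 31 reads. The SVZ difference was -0.46 (exact permutation p = 0.8), -1.08 without the library labelled SVZ knockout replicate 2 and -0.03 without the library labelled SVZ wild type replicate 2. Which part of the gene was deleted is not given in the sources used here. Mir126a and Mir126b, the microRNA genes within Egfl7, were listed at 0 in all libraries.

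**Figure D1:**
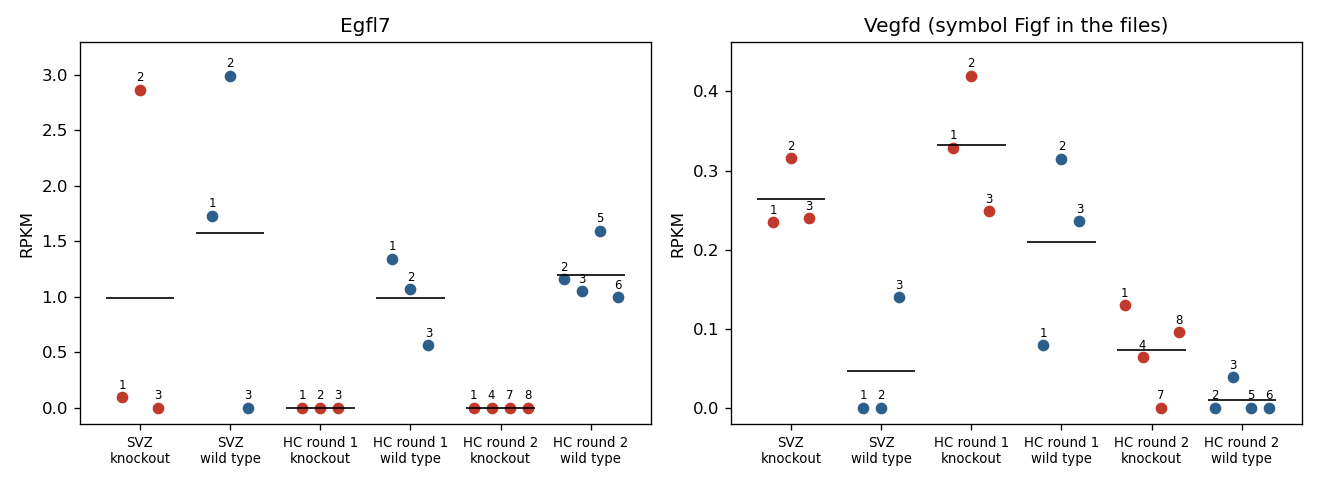
RPKM of Egfl7 (left) and of Vegfd, listed as Figf (right), in each of the 20 libraries; points are libraries with their replicate numbers, red for knockout and blue for wild type, and lines are group means. Egfl7 was 0 in all 7 hippocampal knockouts, while the library labelled SVZ knockout replicate 2 had 2.86 RPKM and the library labelled SVZ wild type replicate 3 had 0.

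Vegfd, a lymphatic and vascular growth factor listed under its older symbol Figf (chromosome X, bases 164372998 to 164402650), was near the detection limit, with 0 to 5 reads per library. Its knockout minus wild-type log2 difference was 0.27 in the SVZ by the labels (exact permutation p = 0.1), 0.14 in HC1 (p = 0.2) and 0.09 in HC2 (p = 0.143). Over HC1 and HC2 together it was 0.11 (exact permutation p = 0.0386), and over all 3 comparisons 0.17 (exact permutation p = 0.002), a combination chosen after the single values were seen. Both include HC1, where donor sex differs along with genotype for this X-linked gene, and the second also rests on the doubtful SVZ labels. Neither can thus be read as an effect of genotype alone. Notch1, a receptor that Egfl7 binds (chromosome 2, bases 26457902 to 26503822), differed by 0.06 in the SVZ by the labels (exact permutation p = 0.9), -0.13 in HC1 (p = 0.1) and -0.11 in HC2 (p = 0.743). It averaged 74.1 ± 16.3 RPKM in HC2 knockouts and 81.0 ± 22.2 in HC2 wild types (SD, n = 4).

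The HC2 libraries compare the genotypes among hippocampal spheres of male donors. The cell cycle list, genes of DNA replication and mitosis, stood higher in the knockouts, with positive log2 differences in 38 of 38 members and a median of 1.23. Examples are Ccnd1, cyclin D1 of the G1 phase (2.04, SE 0.90), Ccnd2, its relative cyclin D2 (1.13, SE 0.51), and Cdk1, the mitotic kinase (1.54, SE 0.76). Markers of the oligodendrocyte lineage stood lower, in 20 of 23 members with a median of -0.38, as with Mbp, a major protein of myelin (-0.87, SE 0.43). The Notch pathway list (median -0.16) and the quiescent stem cell list (median -0.26) were lower too, the latter with Id4 (-1.17, SE 0.47) and Id2 (-0.74, SE 0.30), inhibitors of neurogenic transcription factors. No member of these lists passed the test over all genes, nor adjusted over the list alone, where only Egfl7 in the endothelial list passed (adjusted p = 0.046). The cell cycle mean also varied widely within both genotypes: it was 5.67, 4.0, 5.73 and 3.64 on the log2 scale in the knockouts and 5.93, 2.82, 1.92 and 3.74 in the wild types (exact permutation p = 0.343). Gfap, the filament protein of astrocytes, spread likewise, with 9.96, 84.9, 2.47 and 328 RPKM in the knockouts and 1.33, 114, 536 and 20.8 RPKM in the wild types.

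By camera, 9 lists passed in HC2, and none did so with an estimated correlation or by fry. The adjusted p was 2.42e-16 for the cell cycle, and 0.319 with an estimated correlation. It was 3.57e-05 for the oligodendrocyte lineage (adjusted p = 0.302 with an estimated correlation), 0.000115 for the Notch pathway (0.202 likewise) and 0.000382 for quiescent stem cells (0.319 likewise). Interferon-stimulated genes (median 0.30, adjusted p = 2.6e-05) and immediate early genes, transcription factors induced by growth factors (median 0.26, adjusted p = 0.000729), were higher, both with an adjusted p of 0.302 with an estimated correlation. The antigen presentation list (median 0.17, adjusted p = 0.0246), the hypoxia and glycolysis list (median 0.12, adjusted p = 0.0334) and the Wnt, Shh and BMP list (median -0.14, adjusted p = 0.0334) had 0.319, 0.319 and 0.202 with an estimated correlation. The interferon call was lost without knockout replicate 8 (adjusted p = 0.13), and the quiescent stem cell call without knockout replicate 1 (0.102) or wild type replicate 5 (0.157). The antigen presentation call was lost without knockout replicate 4 (0.379) or 8 (0.126) or wild type replicate 2 (0.535), and the hypoxia call without knockout replicate 7 (0.171) or 8 (0.13) or wild type replicate 2 (0.0567) or 5 (0.436). The Wnt, Shh and BMP call was lost without knockout replicate 1 (0.127), 4 (0.079) or 8 (0.13) or wild type replicate 6 (0.168). With the mean of the cell cycle list as a covariate, the oligodendrocyte (0.0749), Notch (0.268), immediate early (0.644), hypoxia (0.389) and Wnt, Shh and BMP (0.1) calls were lost, and the quiescent stem cell list turned to a median of 0.13 (0.363).

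Of single genes, limma called 4 in HC2, all microRNA genes: Mir6919 (2.37, SE 0.10, adjusted p = 1.5e-10) and Mir344 (1.97, SE 0.30, adjusted p = 0.0163) higher, Mir3104 (-1.47, SE 0.11, adjusted p = 1.34e-06) and Mir344i (-2.25, SE 0.19, adjusted p = 4.94e-06) lower. The lower 2 rest on few reads: Mir3104 came from 1 to 2 reads in each of the 4 wild types and 0 in the knockouts, and Mir344i from 1 to 4 reads and 0. For Mir6919 and Mir344 no whole number of reads could be worked out. Taken over the full gene span, the libraries that held them would have 5.39 to 8.08 reads for Mir6919 and 3.65 to 15.6 for Mir344. A shorter length would give fewer, so these calls rest on few reads too. Mir3104, Mir6919 and Mir344 lie within the longer genes Brsk2, Mgat4b and A230057D06Rik. Mir6919, Mir3104 and Mir344i were listed at 0 in all SVZ and HC1 libraries and in 1 genotype of HC2. Groups without spread thus entered their pooled SE, which does not allow for counting error. The count at an unadjusted p under 0.05 was 644, where 820 are expected by chance, and among protein-coding genes none was called and 476 had such a p. The named genes of smallest p included Ano3, of the anoctamin family of membrane proteins, at 15.3 ± 1.46 RPKM in the knockouts and 8.51 ± 1.13 in the wild types (SD, n = 4; log2 0.78, adjusted p = 0.135). Psrc1, a spindle-associated protein, had 87.2 ± 16.6 and 41.3 ± 19.9 RPKM (log2 1.15, adjusted p = 0.314). Log2 differences of the others were 0.53 for Ccng1, cyclin G1, 0.56 for Prps2, an enzyme of nucleotide synthesis, 0.42 for Wdr35, of ciliary transport, 0.69 for Svop, 1.61 for Scml4, 0.72 for the U5 small nuclear RNA gene Rnu5g, -0.64 for Megf11 and -0.95 for Cd59a, and none passed. Without wild type replicate 2 the count was 26, and without knockout replicate 1 or 4 it was 7. Mir344 was lost without knockout replicates 4, 7 or 8 or wild type replicates 5 or 6, with adjusted p from 0.0553 to 0.0853. A fit on only the HC2 groups lost both Mir344 and Mir344i.

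HC1 compares the genotypes in the first hippocampal round, where the knockout donors were male and the wild-type donors female. Xist, the RNA that silences 1 X chromosome in females (chromosome X, bases 103460373 to 103483233), had 122 ± 38.7 RPKM in the wild types and 0.0407 ± 0.0110 in the knockouts (SD, n = 3; log2 -6.83, SE 0.16, adjusted p = 1.93e-14). The X-linked genes Kdm5c and Eif2s3x, which escape that silencing, differed by -0.45 and -0.53 without passing (adjusted p = 0.171 and 0.324). Genes of cholesterol synthesis stood higher in the knockouts in 23 of 23 members, with a median of 0.30, for example Sqle, squalene epoxidase (0.44, SE 0.32), and Dhcr7, of the last step of the pathway (0.48, SE 0.40). The cell cycle list was higher in 38 of 38 members with a median of 0.47. Its mean on the log2 scale was 5.92, 5.66 and 6.11 in the knockouts and 4.78, 5.80 and 5.66 in the wild types. That of cholesterol synthesis was 6.72, 6.72 and 6.82 against 6.16, 6.72 and 6.49. Both were lowest in wild type replicate 1, which carried much of the difference. Itga6, a laminin receptor subunit, had 74.8 ± 6.97 RPKM in the knockouts and 40.4 ± 8.31 in the wild types (SD, n = 3; log2 0.89, adjusted p = 0.579) and was the only member of the 27 lists to pass adjusted over the list alone (adjusted p = 0.0144).

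limma called 2 genes in HC1, Xist and the X-linked Mir7673 (-2.96, SE 0.43, adjusted p = 0.02), the latter from 1 to 2 reads per library of the first round that held it. The count at an unadjusted p under 0.05 was 646, and no protein-coding gene was called. Mir7673 was lost without any single HC1 library, with adjusted p from 0.0757 to 0.153, and 1 gene was called without knockout replicates 1 or 3 or wild type replicates 1 or 3. Genes of small p that did not pass were Slc10a7 (0.79), Wrb, of tail-anchored protein insertion (1.03), Tusc3, of protein glycosylation (1.1), Gbp5, an interferon-induced GTPase (0.59), Cd59a (-1.29) and Fam89b (-0.65). By camera, 5 lists rose and none did with an estimated correlation: cholesterol synthesis (adjusted p = 0.000295, and 0.886 with an estimated correlation), cell cycle (0.000392 and 0.936), immediate early genes (0.0018 and 0.751, median 0.29), and extracellular matrix and integrin and adhesion (0.0333 and 0.751 each, medians 0.13 and 0.16). By fry 0 passed. Without wild type replicate 1 only 1 list was called, with an adjusted p of 0.309 for cholesterol synthesis and 0.54 for the cell cycle, and without knockout replicate 2 it was 3. The extracellular matrix call was lost without knockout replicate 2 (0.142) or wild type replicate 3 (0.291), and the integrin call without knockout replicate 1 (0.139) or 2 (0.0701) or wild type replicate 3 (0.133).

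Taking both hippocampal rounds together, with each contrast formed within its round, Cd59a was the only protein-coding gene called. Cd59a encodes a membrane-bound inhibitor of the complement cascade and lies on chromosome 2 (bases 104095801 to 104115413). It had 0.222 ± 0.223 RPKM in HC1 knockouts against 1.96 ± 0.142 in HC1 wild types (SD, n = 3), and 0.296 ± 0.375 against 1.5 ± 0.665 in HC2 (SD, n = 4). Its log2 difference was -1.1 (SE 0.17, adjusted p = 0.0203; exact permutation p = 0.00286). In the SVZ it had 0.492 ± 0.532 RPKM in libraries labelled knockout and 0.280 ± 0.124 in those labelled wild type (SD, n = 3; exact permutation p = 0.8). Its call was lost among protein-coding genes alone (adjusted p = 0.0745), among the authors' filtered genes (0.0935), with a pseudocount of 0.1 (0.26), with arrayWeights (0.0587) and with the cell cycle covariate (0.0672). Donor sex as a term leaves only the HC2 contrast (-0.95, adjusted p = 0.521) and says nothing about sex as its source. The call was also lost without any 1 HC1 library except knockout replicate 1 (adjusted p from 0.0733 to 0.0992), and without HC2 knockout replicate 7 (0.0515) or 8 (0.0555) or HC2 wild type replicate 3 (0.0524).

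The cell cycle list rose by camera over both rounds (median 0.81, 38 of 38 positive, adjusted p = 1.29e-13, and 0.682 with an estimated correlation; exact permutation p of its mean 0.149), for example Ccne1, cyclin E1 (0.68, SE 0.29). So did the immediate early list (median 0.31, adjusted p = 4.54e-05, and 0.682 with an estimated correlation), for example Egr1 (0.75, SE 0.25) and Junb (0.51, SE 0.18). The cholesterol synthesis list rose (median 0.15, adjusted p = 0.019, and 0.785 with an estimated correlation). Its rise came from HC1, where donor sex differs too, since the HC2 median was -0.0267 (adjusted p = 0.96), and with the cell cycle covariate it was -0.15 over both rounds. In turn, quiescent stem cell genes (median -0.27, adjusted p = 0.00366), the oligodendrocyte lineage (median -0.25, adjusted p = 0.0177) and the Notch pathway (median -0.11, adjusted p = 0.019) fell by camera, each with an adjusted p of 0.682 with an estimated correlation. In these 3 lists and in the immediate early list 0 members passed in limma, over all genes or over the list alone. With the cell cycle covariate the oligodendrocyte (0.334) and Notch (0.472) calls were lost, and the quiescent stem cell median turned to 0.0283 (0.657). By fry 0 lists passed. Adjusted over the list alone, Itga6 (0.51) passed in the integrin and adhesion list and Egfl7 in the endothelial list. limma called 5 genes, with Xist (-3.42), Mir6919 (1.19), Mir3104 (-0.73) and Mir344i (-1.1) besides Cd59a, and 970 had an unadjusted p under 0.05. The next genes by p were Slc10a7 (0.55, adjusted p = 0.159), Kdm5c (-0.26), Prps2 (0.52), Ccdc73 (0.51), Tusc3 (0.71), Ano3 (0.48), Fam89b (-0.45) and Wdr35 (0.30). The count was 19 without HC2 wild type replicate 2 and 9 without HC2 knockout replicate 1, and 2 lists were called without HC2 wild type replicate 5. The cholesterol call was also lost without HC1 knockout replicate 3 (0.0661), HC1 wild type replicate 1 (0.414), HC2 knockout replicate 1 (0.151) or 7 (0.626) or HC2 wild type replicate 3 (0.0775). The Notch call was lost without HC1 wild type replicate 3 (0.0665), HC2 knockout replicate 1 (0.108) or HC2 wild type replicate 6 (0.0989), the oligodendrocyte call without HC1 knockout replicate 3 (0.23), HC1 wild type replicate 1 (0.161) or HC2 knockout replicate 4 (0.0595), and the quiescent stem cell call without HC2 knockout replicate 1 (0.0528).

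**Figure D2:**
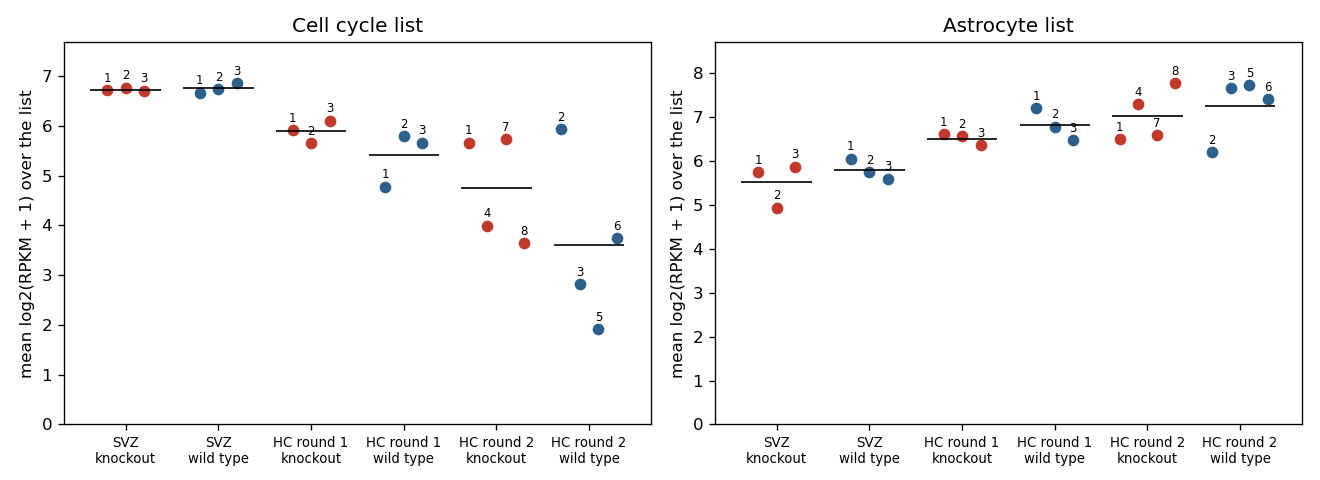
Mean log2(RPKM + 1) over the cell cycle list (left) and the astrocyte list (right) in each library; points are libraries with their replicate numbers, red for knockout and blue for wild type, and lines are group means. The cell cycle mean lay between 6.67 and 6.86 in the SVZ libraries and between 1.92 and 5.93 in the HC2 libraries of both genotypes.

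In the SVZ all directions follow the labels, and the library labelled SVZ knockout replicate 2 and the library labelled SVZ wild type replicate 3 are in doubt through their Egfl7 levels. Antigen presentation genes stood lower in the libraries labelled knockout in all 10 members, with a median of -0.27, for example Tap2, of the peptide transporter (-0.42, SE 0.18), and H2-K1, a class I heavy chain (-0.38, SE 0.22). The list mean on the log2 scale was 2.01, 1.80 and 2.09 in the libraries labelled knockout and 2.10, 2.10 and 2.25 in those labelled wild type. The lowest and the highest mean, 1.80 and 2.25, came from the doubtful libraries. Astrocyte markers stood lower in 15 of 18 members, with a median of -0.28, for example the transporters Slc4a4 (-0.58, SE 0.25) and Slc1a3 (-0.37, SE 0.20). Their list mean on the log2 scale was 5.75, 4.93 and 5.87 in the libraries labelled knockout and 6.05, 5.74 and 5.60 in those labelled wild type. The 4.93 is that of the doubtful knockout replicate 2, and the other knockouts lie within the range of the wild types. Extracellular matrix genes stood higher in 21 of 33 members (median 0.17), among them Col18a1 (1.48, SE 0.64), Col4a6 (1.03, SE 0.46) and Thbs2 (1.18, SE 0.54), while Col4a2 had -0.45 (SE 0.21). The list mean was 3.36, 3.61 and 3.14 in the libraries labelled knockout and 3.11, 3.05 and 3.45 in those labelled wild type. The highest mean under each label came from its doubtful library, so the groups overlap. No member passed, over all genes or adjusted over the list alone. The cell cycle list showed a median of -0.03 (adjusted p = 0.947; exact permutation p of its mean 0.8).

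By camera, 5 lists passed in the SVZ and 0 did with an estimated correlation or by fry. Antigen presentation had an adjusted p of 0.00142 (0.405 with an estimated correlation), astrocytes 0.00619 (0.745), the Wnt, Shh and BMP list 0.0209 (0.112, median -0.15), quiescent stem cells 0.0443 (0.745, median -0.23) and extracellular matrix 0.0461 (0.733). No list was called without the library labelled knockout replicate 2, 2 without knockout replicate 1, wild type replicate 1 or the library labelled wild type replicate 3, 3 without wild type replicate 2, and 1 with both doubtful libraries left out. limma called 2 genes, and 379 had an unadjusted p under 0.05 against 820 expected by chance. Rnu7, the U7 small nuclear RNA that processes histone transcripts (chromosome 6, bases 124741225 to 124741286), was higher by 2.11 (SE 0.22, adjusted p = 0.000377), from 2, 3 and 3 reads in the libraries labelled knockout and 0 in each labelled wild type. It was 0 in every HC1 library as well, so groups without spread entered its pooled SE, which does not allow for counting error. The pseudogene Gm15032 (chromosome X, bases 142622473 to 142625562) was higher by 1.67 (SE 0.21, adjusted p = 0.00366), with 18.2, 21.0 and 23 RPKM in the libraries labelled knockout and 6.02, 7.43 and 4.30 in those labelled wild type. In HC1 it had 20.1 to 24.9 RPKM in knockouts and 7.65 to 14.5 in wild types (log2 0.90, SE 0.21, adjusted p = 0.552), and in HC2 at most 0.282. With both doubtful libraries left out limma called 3 genes, Rnu7 higher and Mir7673 and Egfl7 lower, Egfl7 being the gene by which the libraries were left out, and Gm15032 did not pass (1.48, adjusted p = 0.133). Without knockout replicate 3 the count was 5. In a fit on only the SVZ groups neither Rnu7 (adjusted p = 0.0534) nor Gm15032 (0.19) passed, and with the replicate number as a block as well both had an adjusted p of 1.

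The protein-coding genes of smallest p in the SVZ did not pass. Clk3, a kinase of splicing factors, had 59.9 ± 3.21 RPKM in the libraries labelled knockout and 40.3 ± 5.79 in those labelled wild type (SD, n = 3; log2 0.57, SE 0.11, adjusted p = 0.641). The adjusted p was 1 for the others: Uxt, a prefoldin-like cofactor (0.66), Fam199x (0.48), Clcf1, a cytokine (1.1), Mboat7, a phospholipid acyltransferase (-0.36), the syntrophin gene Sntb1 (-0.61), Angptl6 (-0.57), Dolk, dolichol kinase (-0.33), and Zfp213 (-0.63).

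The difference between the SVZ and HC2 knockout effects, again with the doubtful SVZ labels, passed for 5 genes, 4 higher and 1 lower in the SVZ, and 324 had an unadjusted p under 0.05. They were the microRNA genes Mir344i, Mir3104 and Mir6919, Rnu7 and Gm15032, and no protein-coding gene was called. These microRNA genes were listed at 0 in all SVZ and HC1 libraries, so their pooled SE has the same limit here as in HC2. The count was 8 without HC2 knockout replicate 1. The difference between the HC1 and HC2 effects passed for 4 genes, Xist and the same 3 microRNA genes, with 421 at an unadjusted p under 0.05, no protein-coding gene, and a count of 7 without HC2 knockout replicate 1. By camera, 5 and 7 lists passed, and 0 with an estimated correlation or by fry. Adjusted over the list alone, Tap2 (-0.84) and H2-Q4 (-0.91) of the antigen presentation list passed in the first of these differences.

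The contrast of SVZ with HC2 spheres asks how the regions differ, with culture day and sphere round differing alongside. The cell cycle list was higher in the SVZ in 38 of 38 members, with a median of 2.61, including the replication factors Mcm7 (2.78) and Pcna (2.79), and all 38 passed, over all genes and adjusted over the list alone. Cholesterol synthesis was higher (median 0.71, 16 up and 0 down of 23), with Dhcr7 at 2.57 and Fdps, farnesyl diphosphate synthase, at 2.32. Of 12 heat shock genes 10 were higher and 2, Hspa1a and Hspa1b, lower. Astrocyte markers (median -1.36, 3 up and 14 down of 18) and quiescent stem cell genes (median -1.18, 3 up and 17 down of 24) were lower in the SVZ, including the calcium-binding protein S100b (-3.20), the zinc transporter Slc39a12 (-3.42), Gfap (-3.85) and the lipid carrier Apoe (-5.41). The counts adjusted over the list alone were the same for these lists. Of genes for regional identity, Six3, a forebrain transcription factor of the subventricular list, was higher (3.18), at 14 ± 3.33 RPKM in libraries labelled SVZ knockout and 13.2 ± 2.04 in those labelled SVZ wild type (SD, n = 3), against 0.794 ± 0.682 and 0.674 ± 0.925 in HC2 (SD, n = 4). Zbtb20 (-2.02) and Dmrta2 (-2.40), of the hippocampal list, were lower, while its member Emx2 (1.35) was higher, and the list as a whole (median -0.32, 4 up and 3 down of 9) had an adjusted p of 0.909. None of these 3 genes passed within the first round (Zbtb20 -0.002, Dmrta2 -0.31, Emx2 0.22; adjusted p = 1, 0.83 and 0.586).

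limma called 11027 of 16403 genes between SVZ and HC2, 5686 higher and 5341 lower in the SVZ, and 11454 had an unadjusted p under 0.05. Named genes with a high difference were Tagln2 (4.90), Anp32b (4.81), the ribosomal protein gene Rps29 (4.81) and Hmgn2 (4.51). Those with the lowest were short structural RNAs, the RNase P component Rpph1 (-12.18), the signal recognition particle RNAs Rn7s1 (-11.49) and Rn7s2 (-11.34), Rmrp (-10.93) and Rn7sk (-10.83). Other called members of the regional and cell type lists, several of which turned sign within the first round as given below, were Gsx1 (1.31), Sp9 (-1.17), Acta2 (2.89), Rarres2 (1.21), Foxj1 (-1.25), Dynlrb2 (-0.49), Nefm (2.07), Gap43 (2.02), Gad1 (-2.33), Sox4 (-1.92), Sox9 (0.72), Atp1b2 (0.78), Sox10 (1.62), Ugt8a (0.71) and Gpr17 (-1.52). By camera 5 lists passed, with an adjusted p of 6.21e-07 for the cell cycle and 0.00906 for heat shock, cholesterol synthesis, astrocytes and quiescent stem cells. None passed with an estimated correlation (adjusted p = 0.781 for each), and 19 passed by fry. Rescaling the libraries moved the median of all genes to -0.07 and gave 5180 higher and 6000 lower genes.

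Within the first round, SVZ knockouts against HC1 knockouts gave 1158 genes, 432 higher and 726 lower in the SVZ. Of these, 974 were also called against HC2, and 895 had the same sign in both. Both comparisons share the SVZ knockout libraries, so no number expected by chance is given, and these include the library labelled SVZ knockout replicate 2. Six3 (2.67), the neurofilament gene Nefm (1.48), Slc39a12 (-3.22) and Gad1, the enzyme of GABA synthesis (-1.73), were called in both with the same sign. Anp32b (0.53) and Rps29 (0.40) did not pass within the round, while Rn7s1 (1.85, adjusted p = 0.00898) and Rn7s2 (1.82, adjusted p = 0.0145) were higher in the SVZ, against -11.49 and -11.34 compared with HC2. Of the 30 named genes 12 turned sign within the round. Besides 5 structural RNAs these were Atp1b2 (-1.06), Sox10 (-0.60), Ugt8a (-0.38), Gsx1 (-0.20), Rarres2 (-0.13), Sox9 (-0.12) and Dynlrb2 (0.0191), none of which passed there. The cell cycle (median 0.88) and astrocyte (median -0.86) lists kept their direction by camera (adjusted p = 0.000425 each), with an adjusted p of 0.731 and 0.523 with an estimated correlation. No cell cycle gene passed on its own within the round, against 38 of 38 compared with HC2, and 4 astrocyte genes did. The other 3 lists called against HC2 did not pass: heat shock (median 0.26, adjusted p = 0.0617), quiescent stem cells (median -0.55, adjusted p = 0.0617) and cholesterol synthesis (median -0.005, adjusted p = 0.87). The oligodendrocyte list was lower within the round (median -0.53, adjusted p = 0.0299, and 0.655 with an estimated correlation), against a median of 0.17 compared with HC2 (adjusted p = 0.909). Immediate early genes (median 0.43), extracellular matrix (median 0.46) and subventricular origin (median 0.35) were higher (adjusted p = 0.00124, 0.00124 and 0.0065, and 0.511, 0.489 and 0.442 with an estimated correlation).

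**Figure D3:**
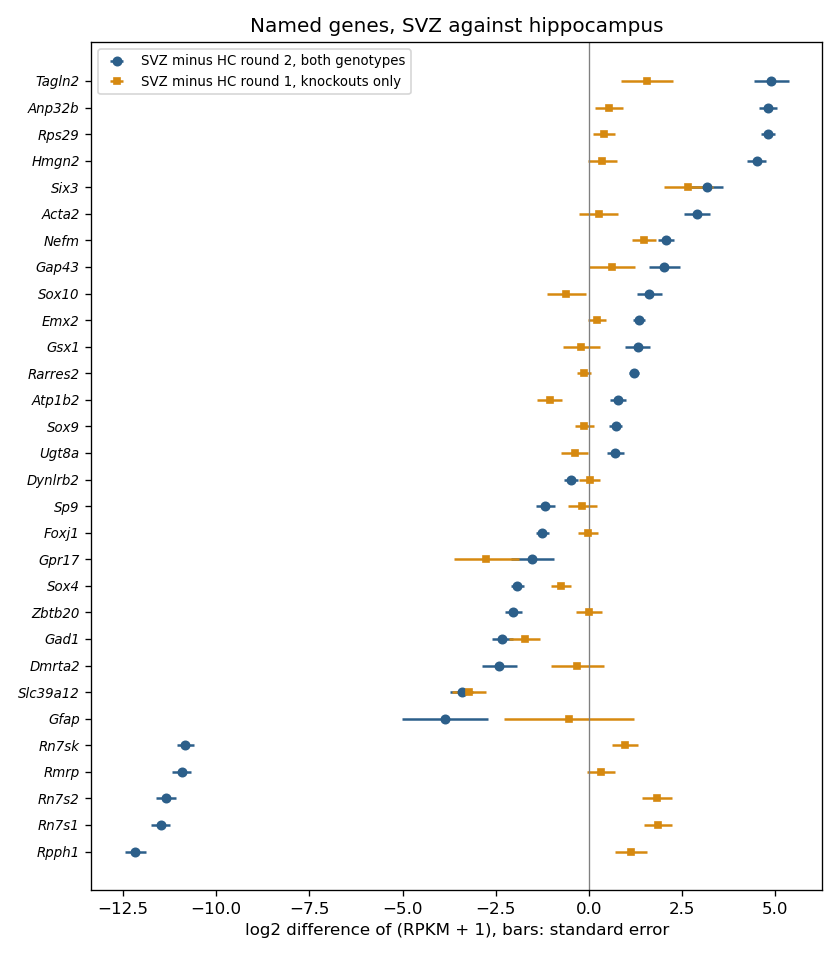
Log2 differences of the named genes between SVZ and hippocampal spheres, with bars for the standard error; blue circles are SVZ minus HC2 over both genotypes and orange squares are SVZ knockouts minus HC1 knockouts. The structural RNAs at the foot lie between -12.18 and -10.83 against HC2 and between 0.31 and 1.85 within the first round.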

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

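The tests of the Egfl7 levels in the SVZ, of the short structural RNAs, of chromosome 2 and of other splits of the libraries were written down after the results were seen; the differences between knockout effects were planned.

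limma's test of the difference between the knockout effects in the SVZ, by its doubtful labels, and in HC2 passed for 5 genes (324 at an unadjusted p under 0.05). The microRNA genes among them were listed at 0 in all SVZ libraries, so their differences come from HC2 alone. The difference was 2.54 for Rnu7 (adjusted p = 0.000497), 2.25 for Mir344i (0.00172), 1.47 for Mir3104 (0.000497), -2.37 for Mir6919 (1.48e-07) and 1.74 for Gm15032 (0.0307). The Gm15032 difference was lost without any 1 SVZ library except wild type replicate 2, and without HC2 knockout replicate 4 or 8 or HC2 wild type replicate 5 or 6, with adjusted p from 0.0608 to 0.146. Of the lists, the effect on the cell cycle differed by -1.24 (adjusted p = 1.59e-09), on the oligodendrocyte lineage by 0.32 (0.00161), on the interferon response by -0.37 (0.000173), on antigen presentation by -0.46 (1.78e-05) and on immediate early genes by -0.33 (0.0107). With an estimated correlation the adjusted p was 0.321 for antigen presentation and 0.603 for the other 4. The interferon call was lost without HC2 knockout replicate 8 (0.0925), and the immediate early call without SVZ knockout replicate 1 (0.0633) or 3 (0.0666), the library labelled SVZ wild type replicate 3 (0.144), HC2 knockout replicate 7 (0.125) or HC2 wild type replicate 3 (0.109).

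Between HC1 and HC2, the difference was -6.83 for Xist (adjusted p = 2.09e-12), whose HC1 contrast is also one of donor sex, 2.25 for Mir344i, 1.47 for Mir3104 and -2.37 for Mir6919 (7.41e-08). The 3 microRNA genes were listed at 0 in all HC1 and SVZ libraries, which were less deep. MicroRNA genes as a class stood lower there too, with a median HC1 minus HC2 difference of -0.95. These differences thus come from HC2 alone, and a like effect could have gone unseen in the first round. Those of Mir3104 and Mir344i rest on few reads. So does that of Mir6919, with at most 8.08 reads per library if the length behind its values is no longer than the gene span. The list medians differed by -0.80 for the cell cycle (adjusted p = 0.0141, and 0.774 with an estimated correlation), -0.43 for the interferon response (5.09e-07 and 0.252), 0.36 for cholesterol synthesis (0.00102 and 0.657), 0.21 for extracellular matrix (0.0157 and 0.388), 0.18 for the oligodendrocyte lineage (0.0134 and 0.525), 0.10 for the Notch pathway (0.0248 and 0.389) and 0.10 for integrin and adhesion (0.0215 and 0.252). The number of lists called was 3 without HC1 wild type replicate 1 or 3, 2 without HC2 wild type replicate 3 and 4 without HC2 wild type replicate 5. Each of the 7 calls except the interferon response was lost in at least 1 omission, with adjusted p from 0.0525 to 0.918.

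A single library lay far from the other 3 of its group in 12 of 172 groups of named genes and lists in HC2. Chance marks about 1 in 20 groups, which is 8.6 here. On the log2(RPKM + 1) scale these were Mir344 in knockout replicate 1 (1.26) and, among wild types, replicate 2 for Prps2 (5.15), Rnu7 (2.60), Anp32b (4.63) and the Notch pathway mean (3.68), replicate 3 for Mir344 (1.32), Vegfd (0.0552), Xist (0.0158) and the sex-linked mean (0.00789), replicate 5 for Mir3104 (1.90) and Sox9 (6.07), and replicate 6 for Dmrta2 (0.523). The values of Vegfd, Xist and the sex-linked list are close to 0.

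Egfl7 went against the label in the library labelled SVZ knockout replicate 2 (2.86 RPKM) and the library labelled SVZ wild type replicate 3 (0). Sampling of few reads was argued against by the 19.7 reads expected in the latter at the lower rate of the other SVZ wild types, and a minor admixture of wild-type RNA by the level of the former, 121% of the mean of those wild types. An exchange of the 2 libraries between the genotypes could not be tested: it needs a partner at 0 in the wild types, whose 3-read limit was 0.265 RPKM, but that library is part of the pattern itself, so it stays open beside separate wrong labels or an outside library, and no biological explanation was tested. Gm15032 and Rnu7 (2, 3 and 3 reads against 0) followed the SVZ labels, but they were called on these labels and so cannot judge an exchange. Vegfd had 3, 4 and 3 reads in the libraries labelled knockout and 0, 0 and 2 in those labelled wild type. Its 2 reads among the wild types lay in the doubtful replicate 3, so with so few reads it cannot judge an exchange either. In HC1 too Gm15032 was higher in all knockouts (20.1 to 24.9 RPKM against 7.65 to 14.5), with 21.0 and 4.30 in the 2 doubtful libraries, but it is X-linked, the HC1 wild types are female and its HC1 difference did not pass (adjusted p = 0.552).

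Short structural RNAs, 33 genes of 7 RNA types, lay lower in the SVZ than in HC2 in 30 genes, with a median of -4.08. Between SVZ and HC1 knockouts both the median and the lower quartile were 0. Genes at 0 in both groups cannot come out lower in the SVZ, so that comparison alone does not judge region or day of culture. HC1, of the same region and day as HC2, lay lower than HC2 in 31 genes, with a median of HC1 minus HC2 of -4.48. That argues against region or day as the cause, and a difference between the rounds may be the cause. RPKM scaling was argued against by a median of -4.14 after rescaling. Whether it arose in the cells, in RNA handling or in the libraries stays open, since sphere round and any library batch differ together.

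Chromosome 2, which carries Egfl7, held more genes at an unadjusted p under 0.05 than the other autosomes in the hippocampal comparisons, a pattern found by scanning all chromosomes over 4 comparisons. Without Egfl7 the share was 5.54% against 3.72% in HC2, 5.62% against 3.68% in HC1 and 9.21% against 5.50% over both rounds. Chance was not excluded: in 25 of 35 splits of the second round, the real one included, some autosome had as large an excess (1.83 points, highest other 6.58). The split with 6.58 had 35.6% of genes on the other autosomes at such a p, so points are not on 1 scale across splits. Counting the whole of chromosome 2 alone, only the real split reached the excess, in HC2 (1 of 35), HC1 (1 of 10) and both rounds (1 of 100). That count does not allow for the scan. DNA within 20 Mb of Egfl7 as the only source could not be judged either, since the excess of 4.30 points beyond that distance over both rounds was exceeded by an autosome in another split (12.5). Over both rounds the share was 7.28% within that distance, above the other autosomes by 1.78 points, and 9.81% beyond it. Counting chromosome 2 alone, the excess within it was reached in 3 of 100 splits, the real one counted (highest other 2.13). On that measure the excess beyond it was reached in 1 of 100 (highest other 2.98). Counting any autosome, the excess of the whole chromosome, 3.71 points, was reached in 31 of 100. A part for DNA carried along with Egfl7 was thus left open.

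Counting the real split, as many genes were called in 17 of 35 splits of the libraries for HC2 (real 4, highest other 3607), 5 of 100 for both hippocampal rounds (5, 26), 13 of 100 for the difference of SVZ and HC2 effects (5, 12) and 15 of 100 for that of HC1 and HC2 (4, 1935), so chance could not be excluded. For HC2, 5 splits called over 100 genes, which points to a structure of the samples that does not follow genotype. Component 1 of the deviations from the HC2 group means held 55.7% of their variance, with 37 of 38 cell cycle genes among its top 500. These deviations leave genotype out by construction, so the component describes spread within the genotypes only. For the regions only the real split gave as many (11027, 5693) among 100 drawn from 3003, a share of 0.01, the smallest possible here. That argues against chance as the source of the count. It does not single out region, since culture day, sphere round and depth differ along with it. For lists the numbers, the real split counted, were 3 of 35 for HC2 (9, 9), 21 of 100 for both rounds (6, 10), 45 of 100 (5, 10) and 10 of 100 (7, 11) for the differences, and 44 of 100 for the regions (5, 9), and chance could not be excluded. The 10 splits of the SVZ and of HC1 cannot give a share under 0.05. With the real one counted, they gave as many genes in 3 (SVZ, real 2, highest other 12) and 3 (HC1; 2, 2), and as many lists in 2 (SVZ; 5, 6) and 3 (HC1; 5, 5).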

How the results depend on the processing

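Protein-coding genes alone, the cell cycle covariate and the omission of both doubtful SVZ libraries were chosen after the results were seen; count-based alternatives such as DESeq2 were not run, because the files hold no counts. Egfl7 stayed lower in knockouts in every omission: from -1.08 (without the library labelled SVZ knockout replicate 2) to -0.03 (without SVZ wild type replicate 2) in the SVZ, -1.14 to -0.85 in HC1 and -1.17 to -1.05 in HC2. Leaving out 1 library gave 2 to 5 genes in the SVZ, 4 to 26 in HC2, 1 to 2 in HC1, 4 to 19 over both rounds, 4 to 8 and 4 to 7 for the differences of SVZ and HC1 from HC2, and 10449 to 11293 for the regions. Lists ranged from 0 to 7, 7 to 11, 1 to 6, 2 to 7, 4 to 7 and 2 to 9, and were 5 for the regions throughout. Replicate numbers do not pair the libraries: deviations of the same number correlated at 0.007, -0.063 and -0.259 in the SVZ and -0.047, -0.115 and -0.029 in HC1. Those of different numbers ran from -0.203 to 0.252 in the SVZ. The 0.252 lay between the libraries labelled knockout replicate 2 and wild type replicate 3, and does not tell whether they were exchanged. Where no reason is given below, the cause was not tested.

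Counts of genes (in brackets at an unadjusted p under 0.05) moved as follows. A pseudocount of 0.1 gave 1 in the SVZ (381). No filter gave 7 in HC2 (1343) and 7 in HC1 (1224). The authors' filtered genes gave 0 in HC2 (845), 0 over both rounds (1191), 1 for the difference of SVZ and HC2 (454) and 1 for HC1 and HC2 (616); the 4 microRNA genes called in HC2 are not among them. limma arrayWeights gave 9 in the SVZ (1558), 8 in HC1 (1239) and 8 over both rounds (1718). A fit on only the groups compared gave 0 in the SVZ (649), but called Egfl7 in HC2 (adjusted p = 0.0371) and over both rounds (0.00045). In HC2 it gave 3 genes (316), Egfl7, Mir3104 and Mir6919, and lost Mir344 and Mir344i. The unadjusted count fell from 644 in HC2 but rose from 379 in the SVZ and from 646 in HC1. Over genes as a whole, the pooled spread may thus understate that of HC2 and overstate that of the SVZ and HC1. Egfl7 in HC2 went the other way, since its adjusted p was 0.988 in the main limma fit. In that fit, the replicate number as a block gave 0 in the SVZ as well (553), and 0 in HC1 (876) against 2 without the block (1173). In HC1, leaving out the sex-linked list gave 1 (645) and leaving out genes on chromosomes X and Y gave 0 (613), both by construction. Protein-coding genes only gave 0 in the SVZ (264), HC2 (476), HC1 (484), both rounds (778) and both differences (229 and 264), since most called genes are not coding, and 9156 for the regions. Both doubtful SVZ libraries left out gave 3 in the SVZ (273), 5 for the difference from HC2 and 9941 for the regions. The cell cycle covariate gave 7 in HC2 (1062) and 4 in HC1 (813). SVZ knockouts against HC1 knockouts gave 1158 genes (4232).

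Counts of lists were 0 with camera's estimated correlation in the SVZ, HC2, HC1, both rounds, both differences and the regions. By fry they were 0 in the same comparisons except the regions, with 19. Median-ratio scaling gave 3 in HC1, the cell cycle covariate 4 in HC2, and both doubtful libraries left out 1 in the SVZ. In the SVZ the antigen presentation call was lost without the library labelled knockout replicate 2 (adjusted p = 0.139) or wild type replicate 3 (0.0664), the astrocyte call without the former (0.702) or wild type replicate 1 (0.188). With the covariate the HC2 call of the cell cycle was lost by construction, since the covariate is that list's mean (0.753), and those of the oligodendrocyte lineage (0.0749), Notch pathway (0.268), immediate early (0.644), hypoxia (0.389), Wnt, Shh and BMP (0.1) and quiescent stem cell (0.363) lists were lost too. Of the list calls with a value in each alternative, 561 were the same, 202 were lost and 4 changed direction.

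Directions that reversed were mostly near 0. Notch1 in the SVZ had -0.11 without the library labelled knockout replicate 2, -0.0566 without wild type replicate 1 and -0.0104 without both doubtful libraries, against 0.25 without knockout replicate 3; Xist there had -0.0019, -0.00358 without wild type replicate 2 and -0.000696, against 0.00431 without wild type replicate 1. In HC2 Notch1 had 0.0216 without knockout replicate 7, 0.0303 without wild type replicate 6 and 0.11 with the covariate, against -0.31 without wild type replicate 2, and Xist -0.000714 without knockout replicate 4, -0.000116 without wild type replicate 2 or 5 and -0.0373 with the covariate, against 0.00418 without wild type replicate 3. Over both rounds Notch1 had 0.0395 and the cholesterol synthesis list -0.15 with the covariate, and with donor sex as a term, which leaves only the HC2 contrast, Xist had 0.0011 and cholesterol synthesis -0.0267. The quiescent stem cell list had 0.13 in HC2 and 0.0283 over both rounds with the covariate. Within the first round the region difference was -1.06 for Atp1b2, 0.0191 for Dynlrb2, -0.20 for Gsx1, -0.13 for Rarres2, 0.31 for Rmrp, 1.85 for Rn7s1, 1.82 for Rn7s2, 0.96 for Rn7sk, 1.13 for Rpph1, -0.60 for Sox10, -0.12 for Sox9 and -0.38 for Ugt8a.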

Other observations

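The genes and tests of this part were chosen after the results were seen.

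Some regional genes were called both against HC2 and within the first round, in comparisons that share the SVZ knockout libraries, the library labelled SVZ knockout replicate 2 among them. Dlx2 and Gsx2, transcription factors of the ventral forebrain, were higher in the SVZ by 0.91 and 0.94 against HC2 and by 0.93 and 0.82 within the round (adjusted p = 0.00936 and 0.0259). Of matrix genes Col18a1 was higher by 3.06 and 3.89, and Spp1, osteopontin, by 3.20 and 2.69. Of adhesion genes Itga5, the fibronectin receptor subunit, was higher by 2.41 and 1.75. The growth factor genes Lif (0.91 and 1.21) and Bdnf (-1.23 and -1.17) went apart. Sparcl1, Apoe and S100b, markers of quiescent stem cells and astrocytes, were lower by -4.13, -5.41 and -3.20 against HC2 and by -3.0, -3.68 and -2.45 within the round. Culture day differs along with region in both comparisons.

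HC1 and HC2 themselves differed in 8904 genes, 5166 higher in the first round and 3738 in the second. Donor sex and depth enter this count too, since the HC1 wild types were female and the second-round libraries deeper. Large parts of the contrast of SVZ with HC2 may thus come from the sphere round, as with the structural RNAs, whose median moved by -4.48 between the hippocampal rounds, and the regions cannot be compared in the second round, which has no SVZ libraries.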
